A study of Mus musculus with 7 samples.

How the data were processed

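Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out against the glucocorticoid receptor (NR3C1), a ligand-activated transcription factor, with an in-house antibody, in mouse embryonic fibroblasts. The cells were wild type or lacked Klf15, which encodes a zinc-finger transcription factor of the Krüppel-like family. They were exposed for 1 h to dexamethasone, a synthetic glucocorticoid, or to ethanol vehicle. The 7 libraries fall into 4 groups by their sample titles: wild type with vehicle (1 library, made from pooled material per the series design), wild type with dexamethasone (2), Klf15-/- with vehicle (2) and Klf15-/- with dexamethasone (2). The labels do not say whether libraries of a group came from separate cultures, so the spread between them may be technical.

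Per the submitters' processing notes, the tools used were CASAVA, Bowtie2 and SAMtools, and the genome build was mm9. The peak caller, its control library and its threshold are not given in the sources used here. Each deposited file is a list of peak summits of a single library, with the chromosome, a position of 1 bp and a score. The score is the authors' value from their peak caller, on a scale that is not stated. The lowest score of a list lay between 3.01 and 3.38. A list called separately per library gets longer with sequencing depth and enrichment, and the read depth of the libraries is unknown from these files. The score was therefore used only to rank or filter summits within their own list, as a percentile from 0 to 100, and no score of one list was set against that of another. Ranks of the same sites within their lists were compared between lists, to name sites and to examine chromosome copy number. Summits lay past the last gene of the supplied GRCm38 gene table on 10 chromosomes, so that table was not used for positions or names. All coordinates are mm9, counted from 1. Planned work that needs an mm9 genome or annotation (the Klf15 locus, gene lists, position relative to genes and sequence motifs) is not analysed here, and sites carry no gene names.

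Summits of all 7 libraries were linked into sites by single linkage, with at most 200 bp between neighbouring summits. A library held a site when it had at least 1 summit in it. The 98170 summits gave 35316 sites, with a median extent of 37 bp and a largest extent of 1190 bp. Overlap of a pair of libraries was given as the Jaccard index, the number of sites held by both divided by the number held by either. Its level by chance came from 100 circular shifts of one list along each chromosome for each of the pairs. Dexamethasone-only sites were those held by both dexamethasone libraries of a genotype with no summit of any of the 3 vehicle libraries. They were classed as shared (all 4 dexamethasone libraries), wild-type only (both wild-type and neither Klf15-/- dexamethasone library) or Klf15-/- only (the reverse). With 2 libraries against 2, an exact two-sided permutation test of the libraries cannot go below p = 0.333. No model of the differences between groups of libraries was fitted, and no p-value is given for them. The 3 splits of the 4 dexamethasone libraries into pairs were compared instead. Wild-type only and Klf15-/- only sites were compared per chromosome by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 21 chromosomes. That test counts sites, which are not independent replicates. Shares have exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

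The design, the alternatives and the rule for named sites were fixed before the data were examined. The rule named the 10 sites of each class with the highest percentile in the library where they ranked lowest, and the 5 such sites held by all 7 libraries. Alternatives were linkage gaps of 100 and 500 bp, the summits above the median score of each list, lists of equal length, autosomes only, other vehicle filters, a single replicate as sufficient, each replicate left out in turn and same-numbered pairs. Another 4 alternatives were chosen after the data were seen: leaving out chromosomes 8, 10, 15, 17 and 19, applying the median score to the dexamethasone lists alone, requiring no summit of the other genotype within 1000 bp, and leaving the summits of 7 windows of X and Y out of the shares per chromosome. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The linkage and classification were tested on simulated lists with planted shared and group-only sites, and 99.5% to 99.8% of the planted number per class was found. Planted sites were put in every list of their class, so the loss of weak sites from a replicate was not simulated. In 100 simulated sets with the observed numbers of group-only sites and no difference between them, some chromosome passed the adjusted threshold of 0.05 in 6. A doubling of chromosome 10 was found in 97 of 100. Sites were drawn independently of each other in these sets, unlike real sites of a chromosome, so both counts hold for that case only.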

Results

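Glucocorticoid receptor occupancy was mapped in 7 ChIP-seq libraries of mouse embryonic fibroblasts, connective-tissue cells grown from embryos. The series compared wild-type and Klf15-/- cells, with and without 1 h of dexamethasone. KLF15 is itself encoded by a glucocorticoid-induced gene. Receptor occupancy at the Klf15 locus is not analysed here, and the genotype labels were not checked. The wild-type vehicle list held 10034 summits. The wild-type dexamethasone lists held 15628 and 16927. The Klf15-/- vehicle lists held 7325 and 8088, and the Klf15-/- dexamethasone lists held 19999 and 20169. No lists were identical.

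The number of receptor summits was higher after dexamethasone in both genotypes. Wild-type cells had 16278 ± 919 summits (mean ± SD, n = 2) against 10034 in the single vehicle library, a ratio of 1.62. Klf15-/- cells had 20084 ± 120.2 (n = 2) against 7707 ± 540 (n = 2), a ratio of 2.61. In each genotype the difference between treatments was several times the spread between libraries. Among dexamethasone lists, those of Klf15-/- cells were longer by a factor of 1.23, with no overlap between the genotypes. Among vehicle lists, the wild-type list was the longest. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333 and no model of list length was fitted, since list length also depends on the read depth, which is unknown.

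**Figure D1:**
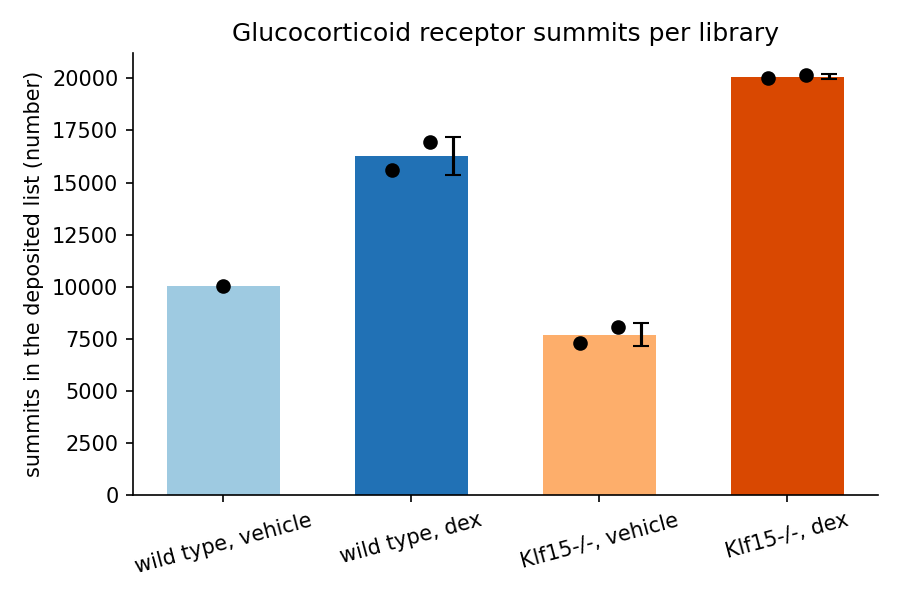
Number of summits in each deposited list (y axis) by genotype and treatment (x axis); bars are group means, points are libraries and error bars are the SD of 2 libraries (wild type with vehicle has 1 library). The 4 dexamethasone lists hold between 15628 and 20169 summits, all above the 3 vehicle lists, which hold between 7325 and 10034.

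Many sites found after dexamethasone were also found without it. In wild-type cells, 12094 sites were held by both dexamethasone libraries. Of these, 7438 had a summit of some vehicle library (61.5%, 95% interval 60.6 to 62.4%), and 4656 had none. In Klf15-/- cells, 14872 sites were held by both dexamethasone libraries. Of these, 8451 had a vehicle summit (56.8%, 56.0 to 57.6%), and 6421 had none. The counts without a vehicle summit rested on both replicates being required: they were 8205 and 7304 without the first or the second wild-type dexamethasone library, and 10655 and 10525 without the first or the second Klf15-/- one. Counting only vehicle libraries of the same genotype, the shares were 53.6% (52.7 to 54.5%) in wild type, with 1 vehicle library, and 43.8% (43.0 to 44.6%) in Klf15-/-, with 2. The share with a summit of any vehicle library was larger among the higher-scoring sites of a list. Over the 4 dexamethasone lists it ranged from 21.2% to 30.5% in the lowest score quintile and from 74.6% to 75.3% in the highest.

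Some of the highest-scoring dexamethasone sites nevertheless had no vehicle summit, in either genotype. The 10 highest-ranked shared dexamethasone-only sites were above the 99.6 percentile in all 4 dexamethasone lists and absent from the 3 vehicle lists. The first was on chromosome 10, from 24116051 to 24116066, and stood at percentiles 99.97 and 99.97 in wild type and 99.98 and 99.88 in Klf15-/-. The second was on chromosome 7, from 71041939 to 71041979, and the third on chromosome 17, from 28557285 to 28557305. The next were on chromosome 15 (78962076 to 78962099) and on chromosome 16 (25059479 to 25059496 and 52094947 to 52094959). The remaining 4 were on chromosome 11 (43805736 to 43805781), chromosome 6 (38785513 to 38785541), chromosome 4 (140979385 to 140979399) and chromosome 17 (47645077 to 47645112). The 5 top-ranked sites held by all 7 libraries were on chromosome 6 (103599202 to 103599225), chromosome 13 (77578218 to 77578234), chromosome 4 (70039202 to 70039211), chromosome 12 (3109923 to 3110013) and chromosome 14 (86598889 to 86598898). Each of these 5 was at or above percentile 99.86 in every list, vehicle lists included. The control library is not given and no regions were filtered out here. Receptor occupancy at these sites therefore cannot be told apart from signal that does not depend on the receptor.

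High-scoring sites were found again in the other replicate, and low-scoring sites often were not. In the highest score quintile, 98.9% to 99.3% of the sites of a dexamethasone library were held by its replicate. In the lowest quintile the range was 38.3% to 47.0%. The Klf15-/- vehicle libraries matched each other less. Library 2 had 85.6% (83.8 to 87.3%) of its highest quintile in library 1, and library 1 had 65.8% (63.2 to 68.2%) of its highest quintile in library 2. For the lowest quintile the shares were 13.9% for library 2 and 41.0% for library 1, the latter within the dexamethasone range.

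**Figure D2:**
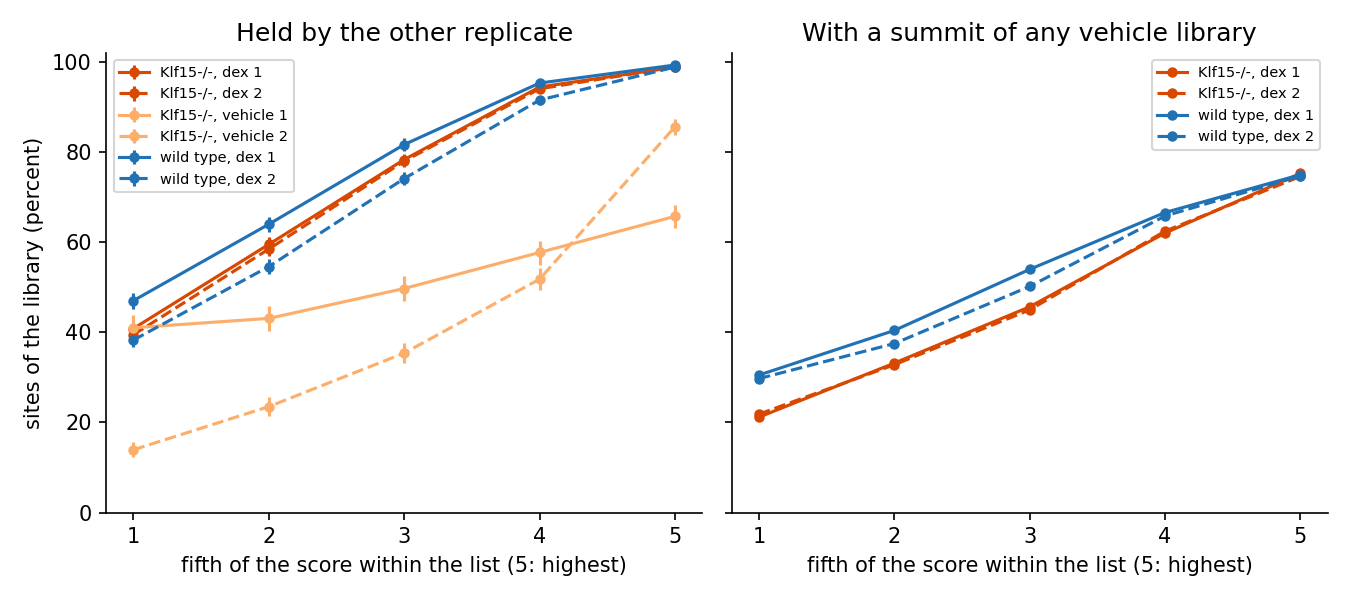
Left, percent of a library's sites held by its replicate, with exact 95% intervals; right, percent of a dexamethasone library's sites with a summit of any vehicle library; both by quintile of the score within the list (x axis, 5 is the highest), with solid lines for replicate 1 and dashed lines for replicate 2. The share held by the replicate reaches 98.9% to 99.3% in the highest quintile of the 4 dexamethasone lists and is 38.3% to 47.0% in the lowest.

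Receptor sites after dexamethasone overlapped between genotypes less than between replicates of a genotype. The Jaccard index was 0.593 between the wild-type replicates and 0.589 between the Klf15-/- replicates. Over the 4 pairs of a wild-type and a Klf15-/- library it was 0.460 ± 0.00604 (SD, n = 4 pairs that share libraries), from 0.454 to 0.465. Shifted lists reached at most 0.00227 in any pair. Lists of equal length gave 0.603 within and 0.475 between genotypes. Vehicle lists overlapped less than dexamethasone lists, with 0.304 between the Klf15-/- replicates. The wild-type vehicle list gave 0.230 with the first and 0.328 with the second Klf15-/- vehicle list, one on each side of the replicate value, so no difference between genotypes was detectable there.

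**Figure D3:**
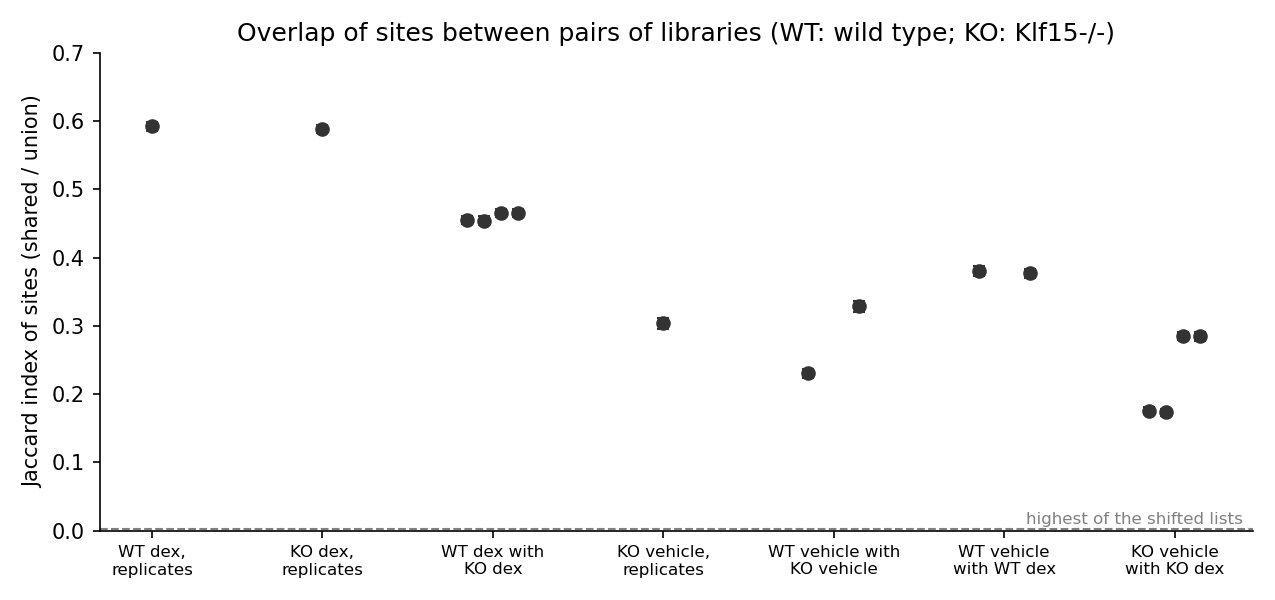
Jaccard index of sites (y axis) for pairs of libraries of the kinds on the x axis; each point is a pair, with its exact 95% interval, which is narrower than most points. The pairs across genotypes with dexamethasone lie from 0.454 to 0.465, below both replicate pairs at 0.593 and 0.589, and shifted lists stay at or below 0.00227.

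The central comparison asked whether loss of Klf15 was accompanied by a different set of dexamethasone-only receptor sites. A missing vehicle summit does not show missing occupancy, since the vehicle lists were shorter and low-scoring sites were often missed even by a replicate. Among sites without a vehicle summit, 2774 were held by all 4 dexamethasone libraries, 1034 by both wild-type libraries alone and 2312 by both Klf15-/- libraries alone. Together, the 3346 genotype-specific sites outnumbered those of the other splits of the same 4 libraries, which gave 704 and 685. These 3 splits cannot give a share below 0.333. Klf15-/- only sites were 2.24 times as many as wild-type only sites, but 1.06 times in lists of equal length. Equal length itself pulls this ratio to 1. Leaving out the first or the second wild-type library gave 3017 and 2535 wild-type only sites and ratios of 0.950 and 1.22. Leaving out the first or the second Klf15-/- library gave 5468 and 5290 Klf15-/- only sites and ratios of 3.70 and 3.64. A genotype left with 1 library need not repeat its sites, so these ratios are pushed towards that genotype. With 1 library of each genotype, in same-numbered pairs and with lists of unequal length, the ratios were 2 (pair 1) and 1.64 (pair 2). Of the wild-type dexamethasone-only sites, 77.8% (76.6 to 79.0%) had a summit in at least 1 Klf15-/- dexamethasone list. Of the Klf15-/- sites, 64.0% (62.8 to 65.2%) had a summit in at least 1 wild-type list. The same libraries also differed by genotype in their summits on chromosome Y, with 75 and 75 in Klf15-/- against 2 and 1 in wild type.

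Genotype-specific sites were mainly low-scoring. A class defined by absence from 2 lists favours such sites. Replicates of the same genotype also missed many of them, with 38.29% to 47.04% of the lowest quintile held. The low scores are therefore not a trait tied to genotype. The median percentile of wild-type only sites was 34.2 and 34.9 in the 2 wild-type lists, and that of Klf15-/- only sites was 36.2 and 36.0 in the 2 Klf15-/- lists. Shared sites had medians from 60.8 to 66.6. Among wild-type dexamethasone-only sites above percentile 80 in both lists, 13 of 636 had no Klf15-/- summit (2.04%, 1.09 to 3.47%). Among Klf15-/- sites above that percentile, 19 of 760 had no wild-type summit (2.50%, 1.51 to 3.88%). Above percentile 90 the counts were 2 of 329 (0.608%, 0.074 to 2.18%) and 3 of 386 (0.777%, 0.161 to 2.25%).

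The highest-ranked wild-type only site lay on chromosome 10, from 97814815 to 97814851, at percentiles 93.0 and 95.7, with the nearest Klf15-/- dexamethasone summit 6.64 kb away. The second lay on chromosome 6, from 82071336 to 82071355, at percentiles 95.7 and 90.1. The third, on chromosome 3 from 99050759 to 99050791, was 96.7 kb from the nearest Klf15-/- summit. The other 7 were on chromosome 12 (25542025 to 25542070), chromosome 10 (18783435 to 18783477), chromosome 8 (36767234 to 36767274), chromosome 16 (34909625 to 34909641 and 31570595 to 31570652), chromosome 7 (144709772 to 144709815) and chromosome 3 (97614450 to 97614483). The first of these on chromosome 16 had its nearest Klf15-/- summit 17.0 kb away and the second 0.445 kb away.

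The highest-ranked Klf15-/- only site lay on chromosome 7, from 65711091 to 65711096, at percentiles 98.1 and 95.6, and 171 kb from the nearest wild-type dexamethasone summit. The second lay on chromosome 2, from 133903922 to 133903940, at percentiles 91.6 and 91.9, and the nearest wild-type summit was 265 kb away. The third lay on chromosome 9, from 112942380 to 112942395, at percentile 91.5 in the list where it ranked lower. The other 7 were on chromosome X (106091022 to 106091117), chromosome 1 (140503601 to 140503634 and 109813705 to 109813749), chromosome 10 (82631610 to 82631627 and 6514681 to 6514703), chromosome 3 (46175064 to 46175072) and chromosome 2 (101263907 to 101263996). The site at 109813705 on chromosome 1 was the most isolated, with no wild-type dexamethasone summit within 1216 kb. The site on chromosome 3 had one at 0.579 kb.

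Without dexamethasone, 5026 of the 9995 wild-type vehicle sites were held by at least 1 Klf15-/- vehicle library (50.3%, 49.3 to 51.3%), and 2536 were held by both. The count was 4452 without the first and 3092 without the second Klf15-/- vehicle library. Of these 2536 sites, 2195 were also held by all 4 dexamethasone libraries (86.6%, 85.2 to 87.9%). The first Klf15-/- vehicle library stood apart from the rest. It had 414 pairs of neighbouring summits under 200 bp apart, against at most 4 in any other library, and 29.4% (28.3 to 30.5%) of its sites were in no other library, against 12.1% and 13.2% in the other vehicle libraries. Without this library, the dexamethasone-only sites numbered 4829 in wild type and 6759 in Klf15-/-, with 1051 wild-type only and 2440 Klf15-/- only sites.

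The genotypes also differed in how their summits were spread over chromosomes. On chromosomes 8, 10, 15, 17 and 19 together, wild-type dexamethasone lists held 26.7% ± 0.18 (SD, n = 2) of their summits and Klf15-/- dexamethasone lists 22.5% ± 0.04 (n = 2). The largest gap was on chromosome 10, with 7.59% ± 0.22 against 6.21% ± 0.13. On chromosomes 1, 7, 9 and 14 the Klf15-/- share was higher by a factor of 1.11 to 1.16. In vehicle lists the corresponding ratios were 1.036, 0.923, 1.02 and 1.11, and with the summits of the X and Y windows described further on left out they were 1.103, 0.978, 1.09 and 1.19. On chromosome 7 the Klf15-/- vehicle libraries lay on either side of wild type, with 2.98% in the first and 4.01% in the second against 3.57% outside these windows. The dexamethasone libraries of the genotypes did not overlap on 16 of 19 autosomes. Chance gives 33.3% for a single chromosome. The autosomes are not separate trials, since all use the same split of the same libraries and the shares of a list sum to a constant. The same 5 chromosomes held 26.9% of summits in the wild-type vehicle list, and 20.4% and 21.9% in the Klf15-/- vehicle lists (22.4% and 22.6% with those windows left out). These chromosomes were those with a ratio of Klf15-/- to wild-type share below 0.9 in dexamethasone lists, a bound chosen after the values were seen.

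Genotype-specific sites were also spread unevenly over chromosomes. By Fisher's exact test, 8 of 21 chromosomes passed an adjusted p of 0.05. Wild-type only sites were over-represented on chromosome 10, which held 9.19% of them against 4.41% of Klf15-/- only sites (exact test, adjusted p = 3.7e-06). In the same exact test they were over-represented on chromosome 15 (8.12% against 4.41%, adjusted p = 0.000194), chromosome 17 (4.74% against 2.34%, adjusted p = 0.00157) and chromosome 8 (6.67% against 4.02%, adjusted p = 0.00433). Klf15-/- only sites were over-represented by the exact test on chromosome 1 (8.78% against 4.55%, adjusted p = 9.7e-05), chromosome 14 (5.02% against 2.42%, adjusted p = 0.00157), chromosome 7 (5.23% against 2.90%, adjusted p = 0.00643) and chromosome 9 (6.01% against 3.58%, adjusted p = 0.00858). Chromosome 19 did not pass (3.10% against 2.16%, exact test, adjusted p = 0.203). With the summits above the median score alone, 3 chromosomes passed. Sites of a chromosome are not independent and are not replicates of a genotype, so these p-values do not measure a difference between genotypes. The sites come from the same summits as the shares per chromosome, so they are not separate evidence of that pattern.

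**Figure D4:**
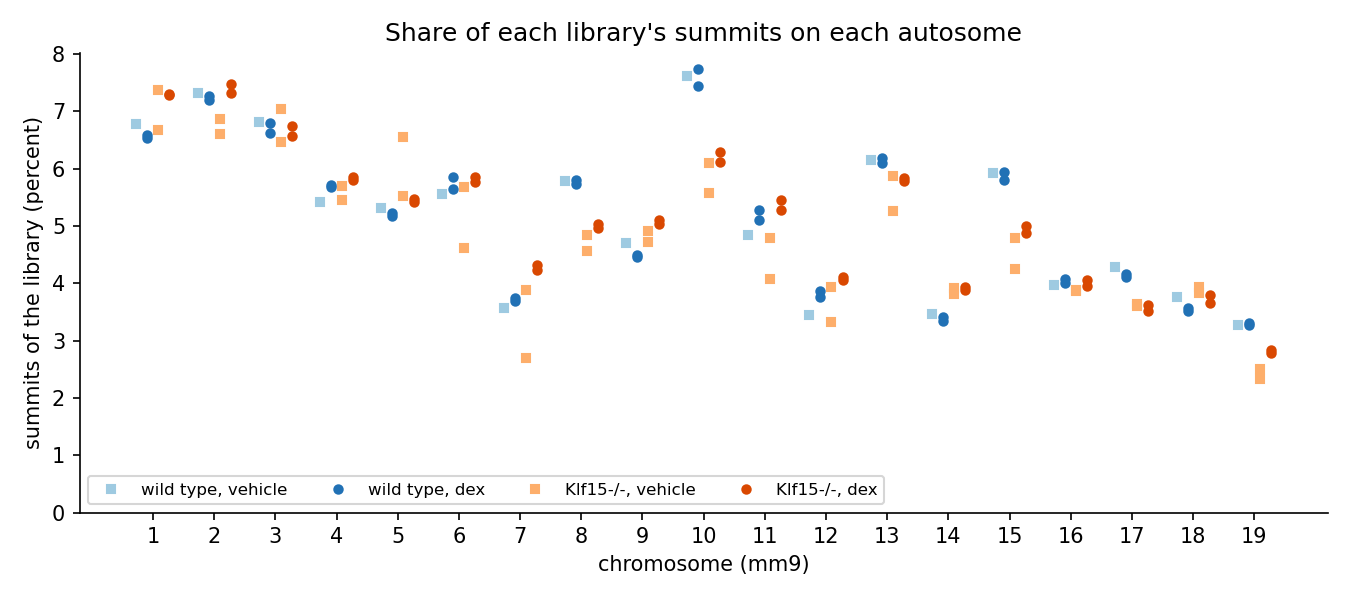
Percent of each library's summits on each autosome (y axis; x axis, mm9 chromosomes), with squares for vehicle and circles for dexamethasone libraries. Wild-type libraries lie above Klf15-/- libraries of the same treatment on chromosomes 8, 10, 15, 17 and 19; on chromosome 10 the dexamethasone means are 7.59% and 6.21%.

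Summits on chromosome Y were almost confined to Klf15-/- cells. The Klf15-/- vehicle lists held 197 and 78 of them and the Klf15-/- dexamethasone lists 75 and 75, against 2 in the wild-type vehicle list and 2 and 1 in the wild-type dexamethasone lists. In windows of 1 Mb, 7 windows held at least 5 summits in each Klf15-/- list and at least 5 times as many as the highest wild-type list, taken as at least 1. These were 2 windows on chromosome Y and 5 on chromosome X, at 51 to 52, 53 to 54 and 120 to 123 Mb. No window met the reverse rule, which was set after the data were seen. Together the windows held 9.21% (8.56 to 9.90%) and 3.08% (2.71 to 3.48%) of the summits of the Klf15-/- vehicle lists. They held 1.16% (1.01 to 1.31%) and 1.05% (0.915 to 1.20%) of those of the Klf15-/- dexamethasone lists, and at most 0.040% (0.011 to 0.102%) of a wild-type list.

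**Figure D5:**
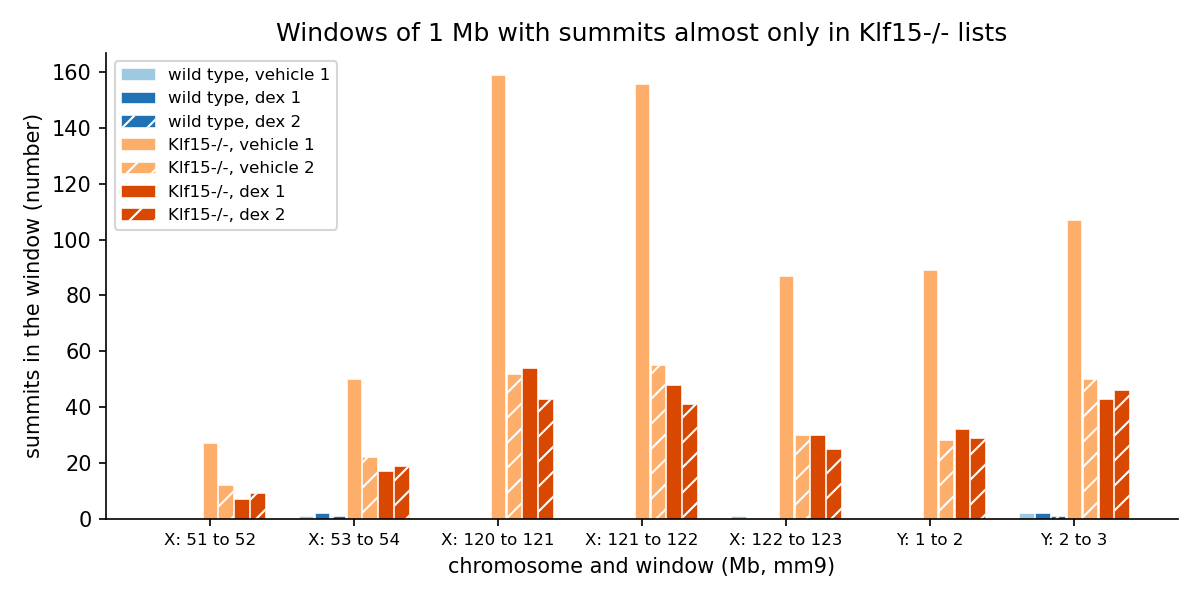
Number of summits (y axis) in each of the 7 windows of 1 Mb (x axis, chromosome and mm9 position) for the 7 libraries, with hatching for replicate 2. Wild-type lists hold at most 2 summits in any window, while the first Klf15-/- vehicle list holds up to 159.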

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

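On 2 chromosomes the share of summits moved in opposite directions with dexamethasone in the genotypes, in every library as deposited. The difference was not tested, and the single wild-type vehicle library has no replicate spread. That list held 734 summits on chromosome 2 and 472 on chromosome 9. Counting error of the changes was not computed, and the 2 chromosomes were flagged for this very pattern. A change in wild type is therefore not shown. On chromosome 2 the mean share changed by -0.0828 percentage points in wild type and by 0.667 in Klf15-/-. On chromosome 9 it changed by -0.223 percentage points in wild type and by 0.258 in Klf15-/-. Part of this came from the summits of 7 windows of X and Y, which made up 9.21% of the first Klf15-/- vehicle list. In a test chosen after the result was seen, leaving them out gave 0.305 on chromosome 2 in Klf15-/-, still a rise in both libraries. On chromosome 9 it gave -0.0036, with shares of 5.20% and 5.06% with vehicle and 5.10% and 5.16% with dexamethasone, so the opposite direction was lost there. No group had enough libraries to test for an outlying one.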

How the results depend on the processing

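Of 169 values recomputed under alternatives, 112 stayed within their bounds, 55 moved and 2 reversed. The bound was 1.5 times for counts of sites and chromosomes, ratios of site counts and the length of the wild-type vehicle list. It was 1 SD for the other list lengths, for shares per chromosome and their ratios, and for Jaccard indices (SD of the between-genotype pairs). Settings chosen after the data were seen are named as such, and where no reason is given the cause was not tested. The excess of within-genotype over between-genotype overlap (0.131) kept its direction throughout. A gap of 100 bp gave Jaccard indices of 0.527 within and 0.419 between genotypes (difference 0.107), and 500 bp gave 0.619 and 0.480 (0.138). Summits above the median score gave 0.611 within (difference 0.145). Fewer summits entered, so the counts of sites were lower: 2659 wild-type and 3636 Klf15-/- dexamethasone-only, 1714 shared, 553 wild-type only and 1226 Klf15-/- only. There were 2617 vehicle sites of both genotypes, and 3 chromosomes passed the threshold. Lists of equal length (15628 summits) gave 0.603 within and 0.475 between, 1305 Klf15-/- only sites and a Klf15-/- to wild-type only ratio of 1.061, because equal lists leave similar numbers unmatched on each side. Autosomes alone left 7085 summits per Klf15-/- vehicle and 19529.5 per Klf15-/- dexamethasone library. Keeping vehicle sites gave 12094 wild-type, 14872 Klf15-/- and 8977 shared sites by construction. A single replicate as sufficient gave 10798, 14676 and 6346, with 4452 wild-type only and 8330 Klf15-/- only. Leaving out each dexamethasone library in turn gave 0.453 to 0.463 between genotypes (difference 0.123 to 0.133). Leaving out each dexamethasone or Klf15-/- vehicle library in turn, but never the single wild-type vehicle library, gave 4653 to 8205 wild-type and 6411 to 10655 Klf15-/- sites, 1051 to 3017 wild-type only, 2440 to 5468 Klf15-/- only, a ratio of 0.950 to 3.70 and, without either Klf15-/- vehicle library, 3092 to 4452 vehicle sites of both genotypes. The lowest ratio came without wild-type dexamethasone library 1 and the highest without Klf15-/- dexamethasone library 1, because a genotype left with 1 library need not repeat its sites. Same-numbered and crossed pairs gave a Jaccard index of 0.460 each, so no pairing by replicate number was seen. So few pairs, which share libraries, cannot exclude a pairing. With the replicate block, pair 1 gave 3208 wild-type only and 6416 Klf15-/- only sites, and pair 2 gave 3811, 6246 and 4365 shared. Chosen after the data were seen, summits above the median of the dexamethasone lists alone gave 1129 shared, 372 wild-type only and 801 Klf15-/- only sites. Also chosen then, leaving out the summits of 7 windows of X and Y gave a Klf15-/- to wild-type ratio of vehicle shares of 0.837 on the 5 chromosomes, 1.09 on chromosome 9 and 1.19 on chromosome 14, and turned the change with dexamethasone on chromosome 9 in Klf15-/- to -0.0036 percentage points, because these summits enter the totals. Alternatives for gene lists, gene positions and motifs were not run, since no mm9 annotation was used here. Read depth is unknown, so the lengths of lists cannot be adjusted for it.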

Other observations

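Of the tests below, those of unequal vehicle libraries, of splits by Klf15 genotype, of dexamethasone on the 5 chromosomes and all on the X and Y windows were chosen after the result was seen. Dexamethasone-only sites often lay near summits of the vehicle lists. Of the 2774 shared sites, 32.2% (30.5 to 34.0%) were within 10 kb of a vehicle summit, against a mean of 9.90% and a highest value of 11.4% over 100 circular shifts of the vehicle lists. The shares were 33.0% (30.1 to 35.9%) for wild-type only and 25.3% (23.5 to 27.1%) for Klf15-/- only sites, each above its highest shift of 13.9% and 11.6%. The shift does not keep the mappable and gene-rich parts of a chromosome in place, so part of the excess may come from where peaks can be called at all.

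Shared dexamethasone-only sites were also uneven at a larger scale. They averaged 1.05 per 1-Mb window over 2649 windows, and 1254 windows held any. The densest window, chosen after the values were seen, was on chromosome 3 from 145 to 146 Mb with 12 sites, followed by chromosome 2 from 167 to 168 Mb with 11. Chromosome 1 from 74 to 75 Mb and chromosome 13 from 5 to 6 Mb held 9 each, and 7 other windows held 8.

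Klf15-/- only sites outnumbered wild-type only sites. The unequal numbers of vehicle libraries are argued against as the source, since the ratio was 2.23 without any removal of vehicle sites. A planned test of list length gave a ratio of 1.06 in lists of equal length, but equal lists pull the ratio to 1 whatever the reason, so that a longer list from deeper sequencing or stronger enrichment cannot be told apart from more occupied sites. A role of the Klf15 genotype stays open because the lists of the genotypes also differ on X, Y and several autosomes. The count of splits decides nothing here, since 3 splits allow no share below 0.333. On autosomes alone, 1001 wild-type only and 2257 Klf15-/- only sites remained (ratio 2.255). Leaving out chromosomes 8, 10, 15, 17 and 19, chosen after the data were seen, gave 705 and 1911 (ratio 2.711). The excess therefore did not rest on sites of X and Y, or on sites of the named autosomes. Autosomes with a larger Klf15-/- share were not left out. Whether the cultures differ in Klf15 alone is not shown by these counts.

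Wild-type lists held a larger share of their summits on chromosomes 8, 10, 15, 17 and 19. The Klf15-/- share was 0.786 of the wild-type share in vehicle lists (0.837 without the X and Y windows), against a response to dexamethasone. It was 0.845 in dexamethasone lists of equal length, against list length. Of 54 windows of 10 Mb there, 92.6% had the larger share in wild type (32.1% of 196 elsewhere), against a few local clusters. Shares of a list sum to a constant, so the lower value elsewhere follows in part from the larger share on these chromosomes. The windows also reuse the dexamethasone lists by which the 5 chromosomes were picked, so part of the 92.6% follows from that choice. A candidate explanation is a different copy number of whole chromosomes in the cultures, for which 8842 autosomal sites held by all 4 dexamethasone lists were ranked: ranks were lower in Klf15-/- beyond the replicate difference on 5 of the 5 chromosomes, and also on 3 of the 14 other autosomes, with 5 of the 14 higher. The median shift was -6.47 percentile points on chromosome 15 but -0.80 on chromosome 17, less than the -1.92 on chromosome 13 and -1.10 on chromosome 6, which are not among the 5. The ranks come from the same libraries as the pattern, an effect of the control library in peak calling was not tested, and the data do not show which genotype departs from the usual copy number.

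Windows of X and Y held summits almost only in Klf15-/- lists. The Klf15-/- vehicle list with fewer of them held 249, more than either dexamethasone list, against a response to dexamethasone, and on chromosome Y as a whole the 3 lists other than the first Klf15-/- vehicle library held at least 75 against at most 2 in wild type, against an origin of the Y part in that library alone. A candidate explanation is that the Klf15-/- cultures contained male cells and the wild-type cultures few or none, with reads of multicopy Y sequences placed on similar X sequences. In dexamethasone lists the share of summits on X outside the windows was 0.902 of that in wild type, but with vehicle it was 2.16% and 1.68% against 1.86%, so it was higher in the first Klf15-/- vehicle library. The genotypes may then differ in the sex of the embryos as well as in Klf15, which these libraries cannot separate.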
